A study of Mus musculus with 22 samples.

How the data were processed

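The series held 22 single-colour Agilent mouse microRNA arrays used here, each as a spot-level file, and 1 value table with a column per sample. The design text in the record speaks of 24 arrays; the other 2 were not analysed here. Scanning and feature extraction used Feature Extraction 10.7.3.1 per the file headers, on 3 slides. Each array carried 49880 non-control spots for 3105 probes of 1247 miRNAs. The processed signal of a spot is a background-corrected fluorescence intensity made by that software, per the file headers. The value table holds log2 intensities that the authors normalised in R 2.15.2, per the submitters' processing notes. RNA was extracted with miRNeasy columns and treated with DNase I, and samples with an integrity number over 8 were kept, per the labels' protocols. The labelling kit named there is the Agilent miRNA complete labelling kit, although another field of the same labels names biotin. A treatment protocol in the labels speaks of HepG2 cells, while all other fields name primary mouse hepatocytes; the cell type written here follows the latter. The probe sequences, genome coordinates and genome build were not used here, so no coordinates are given, and the mmu prefix of the miRNA names is left out.

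The sample names in the value table were checked against the spot files. Quantile normalisation of the total gene signal of the 22 files, a minimum of 0.5 and log2 rebuilt all 22 columns to within 1e-06. Each column was rebuilt by exactly 1 array. The lowest rank correlation of a column with its matched array was 1, and the highest with any other array was 0.966. Only 6 columns held the array filed under their own sample name, and 16 held an array filed under another name. Of these 16, 8 were CsA arrays of the other dose and 8 were DMSO arrays of the other dose series. All 16 exchanges kept the time point and the experiment number, and all lay in experiments 2 and 3. Which of the 2 sources names the samples rightly is not given in the sources used here. The files' own sample names were kept for the main results, because that choice was fixed in the design before the data were examined. The column names of the value table were added as an alternative after the mismatch was seen, and so was a fit with both doses pooled, which is the same under either naming. All column medians of the value table were -1, the log2 of its minimum, so the medians do not show how well the columns were aligned above it. The rebuild by quantile normalisation does, since that method gives all columns 1 common distribution apart from ties.

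The main values were made as follows. The deposited processed signal intensity was averaged over the non-control spots of a probe that the software had not marked as a non-uniform or population outlier. It was divided by the array's 75th percentile over the 281 probes well above background on all arrays; this percentile ran from 188 to 605. Values were floored at 0.0471 and put on a log2 scale, so the floor was -4.41. A probe counted as well above background on an array when at least a share of 0.5 of its spots did, and 14.4% of probe-array pairs passed. Each miRNA was represented by its brightest probe. Tests covered the 289 miRNAs well above background on at least 3 arrays. Control spots took no part in any value. No spot was saturated (0 spots). For a miRNA seen on only some arrays of 1 group the floor makes the fold change a lower bound under this processing, and for 1 seen on only some arrays of both groups it leaves the size open. Arrays held at the floor also vary less, so the SEs and p-values of such miRNAs overstate the precision.

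Differences were tested in R 4.3.3 with limma 3.58.1, in 1 linear model over the 6 groups with moderated variances, and adjusted over 289 miRNAs by the Benjamini-Hochberg method. A miRNA was called at an adjusted p under 0.05; the number that also changed over 1.5-fold is given beside it. A miRNA was called separate where all arrays of 1 group lay on the same side of all arrays of the other. The chance given beside a count of separate miRNAs is a percent of the 289 tested, not a count. Named lists of miRNAs were tested with camera at a set correlation of 0.01 and again with the correlation estimated from the data, adjusted over 13 lists. The rotation test fry was run on the same lists. The 13 tested lists were hepatocyte-enriched, miR-17/miR-92a and paralogous clusters, p53-responsive, NF-kB and inflammation, endoplasmic reticulum stress-linked, lipid and cholesterol metabolism, let-7 family, miR-30 family, miR-29 family, miR-15/16 family, miR-23/24/27 clusters, Dlk1-Dio3 imprinted cluster, and the Sfmbt2 intron cluster, which is the miR-297, miR-466, miR-467 and miR-669 families. Lists with 1 tested member (hypoxia, mesenchymal and stellate, endothelial, leukocyte and macrophage) are given by that member. The erythroid list (2 members on the array, 0 above background), the miR-200 family (5 and 0), the miR-181 family (4 and 2 on any array) and the muscle and neuron list (10 and 1) had no tested member.

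The miRNAs named in the text follow a rule written before the data were examined. For each CsA comparison these are the 10 called miRNAs with the largest rise and the 10 with the largest fall among those that were separate. Where fewer than 10 were called, the 5 with the lowest unadjusted p were added. Up to 4 members with the lowest p were taken from each list. For the dose, time and interaction comparisons the 5 largest rises and 5 largest falls were taken. Always named are miR-122-5p, miR-192-5p, miR-21a-5p, miR-34a-5p, miR-29b-3p and miR-200b-3p. Any further miRNA is marked in the text as named after its values were seen. The lists, the scaling, the tests, the main sample names and most alternatives were likewise fixed before the data were examined. The alternatives added after the files were read are the value-table names, the pooled doses, and a fit without 3 arrays that stood apart.

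The replicates are biological replicates per the labels. Each label also carries a number from 1 to 3 written Ex., read here as an experiment number, whose meaning is not given in the sources used here, and a tag for 1 of 2 dose series; DMSO arrays carry the tags too, 3 and 2 arrays at 24 h and 3 and 3 at 48 h. Groups of 2 to 6 arrays limit precision. In simulations with 60 changed miRNAs, a log2 change of 1 was recovered for 66.5% of miRNAs at 10 µM and 24 h, 58% at 50 µM and 24 h, 69% at 10 µM and 48 h and 68% at 50 µM and 48 h. A log2 change of 0.5 was recovered for 21.5% to 29%, and the false share among the calls was 3.30% to 5.02%, all with the files' names. With the value-table names a log2 change of 1 was recovered for 71.75% to 80.5%, with a false share of 3.08% to 5.84%. The simulated noise was independent between miRNAs, so these shares may not hold where miRNAs of 1 array move together. Simulated lists of 9 miRNAs moved by a log2 change of 1 were found in 20 of 20 runs at the set correlation. Unmoved lists were called there in 0 or 1 of 20. Those lists were drawn at random with the same independent noise, so the runs do not cover families whose members move together. The test with the correlation estimated was not simulated, so the weight of a list call lost with it is unknown. The median residual SD was 0.384 log2 with the files' names, 0.318 with the value-table names and 0.376 with doses pooled.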

Results

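Primary hepatocytes of C57Bl6 mice were exposed to cyclosporin A (CsA), a calcineurin inhibitor used against graft rejection that can damage the liver, at 10 µM or 50 µM, or to 0.5% DMSO. Cells were taken after 24 h and 48 h and their miRNAs were measured on arrays. By the array files there were 3 arrays at 10 µM and 2 at 50 µM after 24 h, 3 and 3 after 48 h, and 5 and 6 DMSO arrays. The questions were which miRNAs CsA changed, whether dose mattered, and what culture time alone did. The array files and the value table of the series disagreed on the sample names: 16 of 22 columns held an array filed under another name. For CsA arrays the other name was always the other dose. Every dose result is therefore given under both namings, by the files first and by the value table after it, and a result with both doses pooled is the same under either.

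The liver miRNA miR-122-5p took a mean of 9.76% of the summed miRNA signal (range 6.72% to 14.0% over 22 arrays). The brightest entries were miR-6366 with 17.5% (4.73% to 37.6%) and miR-5109 with 16.2%, followed by miR-3963 with 7.58%, miR-6243 with 5.97% and miR-21a-5p with 5.39%. These entries, and the largest risers such as miR-5105 and miR-6243, are named as on the array, and whether each is a true miRNA was not tested. The 10 brightest entries took 67.3% to 79% of an array's signal. The scanner software listed 201 to 400 miRNAs per array as detected, and the 75th percentile used for scaling ran from 188 to 605. Outlier spots made up 2.19% to 10.3% of an array. The negative controls averaged 0.674 to 33.7 on the DMSO arrays and 215.3 on array CsA10uM_24h replicate 3 (file names). Members of the miR-200 family, which mark other epithelia, were not seen: miR-200b-3p was above background on 0 arrays.

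**Figure D1:**
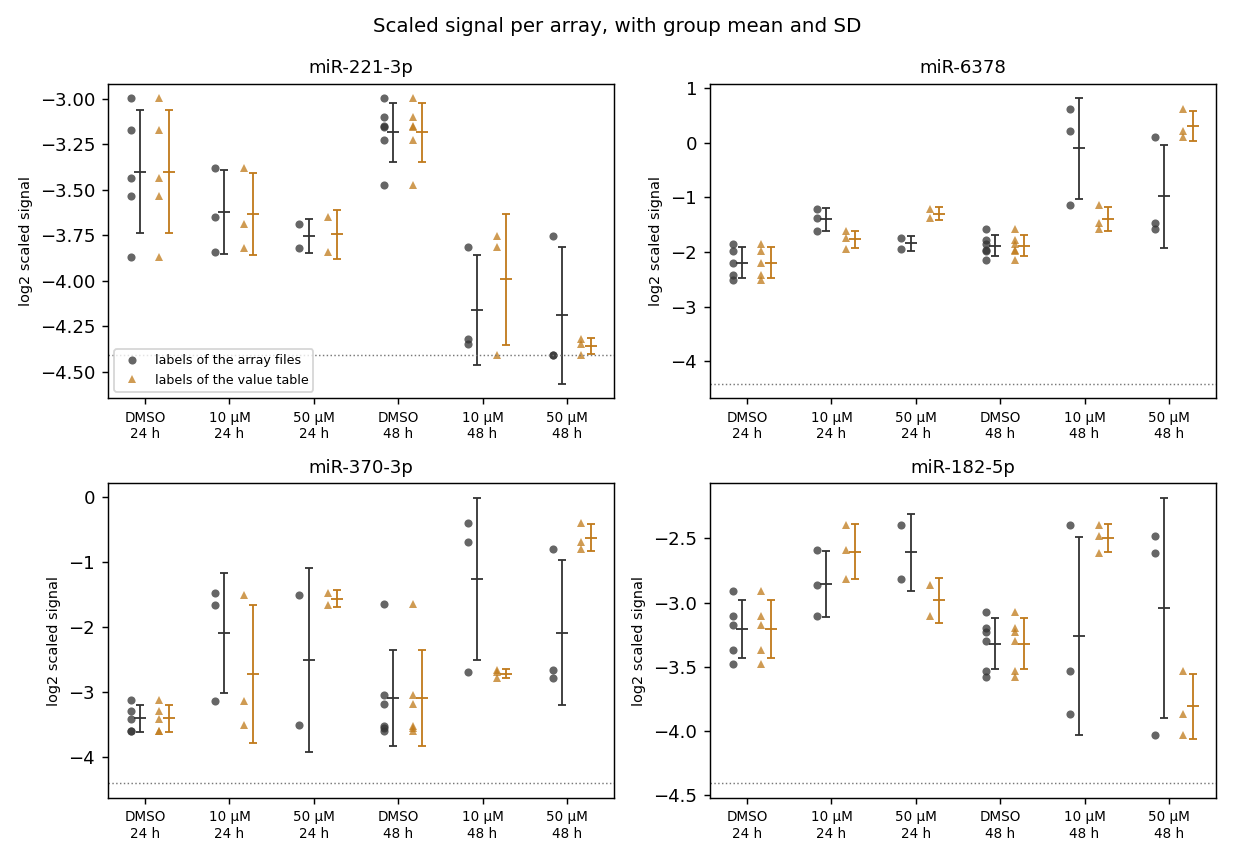
Log2 scaled signal (y axis) of miR-221-3p, miR-6378, miR-370-3p and miR-182-5p on each array by group (x axis), with group mean and SD, grouped by the array files (circles) or the value table (triangles). The dotted line is the floor of -4.41.

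After 24 h at 10 µM, by the files, the lowest p among the tested miRNAs was that of miR-3096b-3p, 2.16-fold higher in CsA, with a log2 change of 1.11 ± 0.28 (SE, n = 3 and 5, adjusted p = 0.277). Its mean was -0.09 ± 0.09 in CsA and -1.20 ± 0.61 in DMSO (SD). Values for miR-6402 (-1.23 ± 0.38, above background on 1 of 3 CsA arrays), miR-5100 (-1.25 ± 0.43), miR-500-3p (0.37 ± 0.13) and miR-487b-3p (-0.50 ± 0.18, above background on 0 of 3 CsA and 3 of 5 DMSO arrays) had adjusted p = 0.571 each. The hepatocyte miRNA miR-122-5p differed by 0.15 ± 0.11 (adjusted p = 0.857). In limma 0 miRNAs passed, and 21 had an unadjusted p under 0.05, 15 of them higher. Of 289 miRNAs 10 were separate, no excess over the 3.57% that chance gives. Without DMSO_24h replicate 1 the count was 1, with miR-3096b-3p at 1.31. The Sfmbt2 intron cluster was lower, with a median log2 change of -0.26 and mean of -0.29 over 11 members, 10 of them negative (camera adjusted p = 0.0149, adjusted p = 0.984 with an estimated correlation). Blocked by slide, its median was -0.27 (adjusted p = 0.046), within slides 2 and 3 it was -0.82 and 0.00, without CsA10uM_24h replicate 1 it was -0.16 (adjusted p = 0.175), and without DMSO_24h replicate 5 it was 0.20 (adjusted p = 0.937). The miR-17/miR-92a list had a median of 0.38 (adjusted p = 0.104). The NF-kB list had a median of 0.15 and a mean of -0.18, while the test leaned down; the p53 and hepatocyte-enriched medians were 0.09 and 0.02, also with the test leaning down.

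Named by the value table, the 10 µM arrays at 24 h gave 0 calls in limma with 16 unadjusted p under 0.05 and 8 separate miRNAs. The lowest adjusted p belonged to miR-182-5p, of the cluster with miR-183 and miR-96, at 0.60 ± 0.15 (adjusted p = 0.242), and miR-183-5p stood at 0.36 ± 0.14 (adjusted p = 0.641). Values for miR-6402, miR-5100 and miR-212-3p were -1.11 ± 0.39 (above background on 1 of 3 CsA arrays), -1.21 ± 0.43 and -1.22 ± 0.44 (SE, n = 3 and 5). The Sfmbt2 intron cluster had a median of -0.34 (adjusted p = 0.0925, with slide as a block -0.40, adjusted p = 0.0233) and the miR-17/miR-92a list 0.29 (adjusted p = 0.0973).

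After 24 h at 50 µM, by the files, 2 arrays were set against 5. The values with the lowest p were miR-483-3p at 1.08 ± 0.40, miR-378a-3p, an intronic miRNA of Ppargc1b, at -0.39 ± 0.16, miR-212-3p at -1.27 ± 0.51, miR-1196-5p at 1.70 ± 0.70 (above background on 4 of 5 DMSO arrays) and miR-5100 at -1.19 ± 0.50 (SE, adjusted p = 1 each). The liver miRNA miR-122-5p differed by 0.03 ± 0.13. In limma 0 miRNAs passed, and 7 had an unadjusted p under 0.05. Of 289 miRNAs 10 were separate, fewer than the 9.52% that chance gives. No list passed (lowest adjusted p = 0.825; 0.992 with an estimated correlation). The miR-23/24/27 clusters had a median of -0.03 and a mean of 0.06.

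Under the value-table names, the 50 µM arrays at 24 h held 11 higher and 0 lower miRNAs, 10 of them over 1.5-fold. The count was 1 with controls of the same tag and 2 with no filter on dim probes. Largest was miR-5105, 5.84-fold higher with 2.55 ± 0.50 (SE, n = 2 and 5, adjusted p = 0.00813), then miR-3473b (1.95 ± 0.37), miR-6243 (1.88 ± 0.39), miR-370-3p (1.84 ± 0.46, 3.59-fold, adjusted p = 0.0222), miR-3473a (1.57 ± 0.35), miR-5622-3p (1.51 ± 0.33) and miR-5119 (1.13 ± 0.25). Of the Dlk1-Dio3 imprinted cluster, which is little expressed in adult liver, miR-494-3p rose by 0.92 ± 0.21 (adjusted p = 0.01) and miR-770-3p by 0.78 ± 0.08 (at least 1.72-fold, above background on 3 of 5 DMSO arrays, adjusted p = 1.76e-06). The entry miR-6378 rose by 0.90 ± 0.19 (adjusted p = 0.00834); miR-5116, named after its values were seen, was the 11th call. All these were higher on both CsA arrays than on all 5 DMSO arrays. Replicate 3 of these CsA arrays is the array filed as CsA10uM_24h replicate 3, on which the negative controls averaged 215.3. A slide block left miR-770-3p at 0.79 (adjusted p = 1.62e-05) and miR-5105 2.59 (adjusted p = 0.0213); within slides 2 and 3, miR-5105 stood at 2.48 and 2.12, miR-370-3p at 2.04 and 1.47 and miR-770-3p at 0.75 and 0.80. limma gave 41 unadjusted p under 0.05, and 51 miRNAs were separate where chance gives 9.52%. Of the 11 calls, 9 were above background on every DMSO array. The count fell to 3 without CsA50uM_24h replicate 2 and to 1 without replicate 3, and was 19 without DMSO_24h replicate 3 (value-table names). The Dlk1-Dio3 list had a median of 0.46 with 2 members higher; camera gave no list (lowest adjusted p = 0.139), while fry gave this list an adjusted p = 0.00166.

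After 48 h at 10 µM, by the files, miR-6378 rose 3.43-fold, a log2 change of 1.78 ± 0.34 (SE, n = 3 and 6, adjusted p = 0.0103), from -1.88 ± 0.19 in DMSO to -0.10 ± 0.92 (SD). The imprinted miR-770-3p rose by 1.22 ± 0.31 (at least 2.33-fold, above background on 2 of 6 DMSO arrays), miR-450a-2-3p by 0.76 ± 0.19 (above on 2 of 3 and 1 of 6 arrays), miR-1906 by 0.58 ± 0.15 (1.49-fold) and miR-500-3p by 0.51 ± 0.12 (1.42-fold), each with adjusted p = 0.0386. The cell-cycle miRNA miR-221-3p, which represses Cdkn1b, fell by 0.98 ± 0.19 (1.97-fold, adjusted p = 0.0103, above on 2 of 3 CsA arrays), and miR-27b-3p, a regulator of lipid genes, fell by 0.76 ± 0.22 (adjusted p = 0.0467) without being separate. Liver miRNAs stood at 0.14 ± 0.11 for miR-122-5p (adjusted p = 0.474) and -0.26 for miR-192-5p (adjusted p = 0.372). Outside the hepatocyte-enriched list, miR-21a-5p stood at -0.39 (adjusted p = 0.353). In all, 16 miRNAs rose and 2 fell, 14 of the 18 over 1.5-fold; 12 of the 16 were at background on some DMSO arrays and 4 were above it on all of them. limma gave 74 unadjusted p under 0.05, and 8 of 289 miRNAs were separate, close to the 2.38% that chance gives.

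These calls at 10 µM leaned on single arrays, and more were called with the experiment number as a block, as given below. The count was 0 without CsA10uM_48h replicate 2 or without replicate 3, 88 without replicate 1, 67 without DMSO_48h replicate 5, 3 without replicate 2, and 2 without replicate 1, 3, 4 or 6 of DMSO (file names). Without CsA10uM_48h replicate 2 the value of miR-6378 was 1.62 and that of miR-221-3p -0.90, and without replicate 3 these were 1.42 and -0.88. When slide was a block 3 calls stayed: miR-6378 at 1.64 ± 0.36, miR-221-3p at -0.87 ± 0.18 and miR-500-3p at 0.58 (adjusted p = 0.0361 each), while miR-770-3p at 1.05 and miR-450a-2-3p at 0.67 had adjusted p = 0.155. Within slides 1 and 3, miR-6378 stood at 2.56 and 0.73, miR-770-3p at 1.76 and 0.26 and miR-221-3p at -1.19 and -0.69. The 16 risers had a median of 1.23 within slide 1, all positive, and of 0.07 within slide 3, where 9 were positive. The median change of all 289 miRNAs was 0.12; it was -0.20 when scaled over all probes and -0.02 after quantile normalisation, and these left 0 and 3 calls (2 higher and 1 lower).

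Among the lists at 10 µM and 48 h, by the files, the miR-23/24/27 clusters were lower: median -0.56, mean -0.50, 5 of 5 members negative, 1 called, and 1 when adjusted over the list alone (camera adjusted p = 0.0218, adjusted p = 0.622 with an estimated correlation). Blocked by slide, their median was -0.43 (adjusted p = 0.0303), and within slides 1 and 3 it was -0.37 and 0.23; the call was lost without CsA10uM_48h replicate 3 (adjusted p = 0.081) and DMSO_48h replicate 2 (adjusted p = 0.054). The other lists did not pass. Medians were -0.15 for let-7 and -0.05 for endoplasmic reticulum stress-linked (adjusted p = 0.0533 each), -0.10 for miR-17/miR-92a (0.0809), -0.20 for p53-responsive (0.0981), -0.14 for lipid and cholesterol metabolism and 0.59 for Dlk1-Dio3 (0.0988 each). Further medians were -0.01 for hepatocyte-enriched, -0.10 for miR-30, -0.09 for miR-29, 0.01 for miR-15/16 with a mean of -0.10, -0.19 for NF-kB, and 0.08 for Sfmbt2, where the test leaned down. Called members adjusted over the list alone were 2 higher in Dlk1-Dio3, 1 lower in hepatocyte-enriched, and 1 higher and 1 lower in lipid.

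The arrays that the value table names 10 µM at 48 h held 2 higher miRNAs and 1 lower. The cluster mates miR-182-5p and miR-183-5p rose by 0.82 ± 0.15 (1.77-fold, adjusted p = 0.00713; -2.50 ± 0.11 against -3.32 ± 0.20, SD) and 0.66 ± 0.13 (1.58-fold, adjusted p = 0.0161), and their neighbour miR-96-5p stood at 0.74 ± 0.21 (adjusted p = 0.15). The cell-cycle miRNA miR-221-3p fell by 0.81 ± 0.17 (at least 1.75-fold, n = 3 and 6, adjusted p = 0.0181, above background on 2 of 3 CsA arrays). With slide as a block these were 0.85 (adjusted p = 0.016), 0.65 (adjusted p = 0.0296) and -0.82 (adjusted p = 0.016); within slides 1 and 3 they were 0.82 and 0.79, 0.70 and 0.60, and -1.26 and -0.66. limma gave 15 unadjusted p under 0.05. All 3 calls were lost without CsA10uM_48h replicate 2 (value-table names), when scaled over all probes and after quantile normalisation. No list passed: the miR-17/miR-92a median was 0.32 (adjusted p = 0.0737, with slide as a block 0.39, adjusted p = 0.0235) and the Sfmbt2 median -0.32 (adjusted p = 0.0737).

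After 48 h at 50 µM, by the files, miR-221-3p was the only call. It fell by 1.01 ± 0.19 (at least 2.01-fold, n = 3 and 6, adjusted p = 0.0147), to -4.19 ± 0.37 from -3.18 ± 0.16 (SD), and was above background on 1 of 3 CsA arrays. Values for miR-130a-3p (-0.82 ± 0.22, adjusted p = 0.189), miR-378b (-0.58 ± 0.19), miR-185-5p (-0.70 ± 0.23) and miR-378a-3p (-0.38 ± 0.13, adjusted p = 0.559) did not pass, and miR-122-5p stood at -0.00 ± 0.11. With slide as a block miR-221-3p kept -0.90 ± 0.18 (adjusted p = 0.0412), and within slides 1 and 3 it was -1.26 and -0.63. The call was lost without CsA50uM_48h replicate 1 or replicate 2, at -0.90 without either. limma gave 18 unadjusted p under 0.05, and 9 of 289 miRNAs were separate, close to the 2.38% that chance gives. No list passed: let-7 had a median of -0.17 (adjusted p = 0.1), p53-responsive -0.25, lipid -0.14, miR-30 -0.15, miR-23/24/27 -0.15 and Dlk1-Dio3 0.37 (adjusted p = 0.116 each). The miR-29 list had a median of 0.06 and a mean of -0.01.

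The arrays that the value table names 50 µM at 48 h held by far the most changes: 79 miRNAs rose and 30 fell, 94 of them over 1.5-fold. Largest was miR-5105, 8.89-fold higher with 3.15 ± 0.43 (SE, n = 3 and 6, adjusted p = 1.7e-05), then miR-5622-3p (2.49 ± 0.28), miR-370-3p of the Dlk1-Dio3 region (2.47 ± 0.39, 5.53-fold, adjusted p = 7.45e-05; -0.62 ± 0.21 against -3.09 ± 0.74, SD), miR-6243 (2.26 ± 0.33), miR-6378 (2.19 ± 0.16, 4.57-fold, adjusted p = 6.04e-09), miR-5121 (2.07 ± 0.53), miR-1306-3p (2.02 ± 0.31), miR-3473b (1.81 ± 0.32), miR-770-3p (1.70 ± 0.06, at least 3.26-fold, above background on 2 of 6 DMSO arrays, adjusted p = 2.44e-13) and miR-3102-3p (at least 1.61 ± 0.20, above on 1 of 6 DMSO arrays). Imprinted miR-494-3p rose 2.70-fold (1.44 ± 0.18, adjusted p = 5.8e-06), and miR-155-5p, a leukocyte and inflammation miRNA, rose by 0.73 ± 0.17 (adjusted p = 0.00293, above on 2 of 3 and 4 of 6 arrays). Among the falls were miR-5097 (-1.91 ± 0.47), miR-6366 (-1.30 ± 0.44), miR-125a-5p (-1.23 ± 0.27, above on 2 of 3 CsA arrays), miR-221-3p (-1.17 ± 0.17, at least 2.26-fold, above on 1 of 3, adjusted p = 4.28e-05), miR-185-5p (-1.07 ± 0.17), miR-130a-3p (-0.99 ± 0.19), miR-27b-3p (-0.97 ± 0.17), miR-18a-5p (-0.92 ± 0.31, above on 2 of 3), miR-28a-5p (-0.92 ± 0.22, above on 2 of 3) and miR-24-3p (-0.86 ± 0.19, adjusted p = 0.0019).

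Liver miRNAs in that comparison were split. The level of miR-122-5p was steady at 0.05 ± 0.11 (adjusted p = 0.713), while miR-192-5p fell by 0.47 ± 0.14 (adjusted p = 0.015) and miR-193a-3p by 0.84 ± 0.23 (adjusted p = 0.00709). Outside the hepatocyte-enriched list, miR-21a-5p fell by 0.69 ± 0.17 (1.62-fold, adjusted p = 0.00348, not separate). The p53 target miR-34a-5p stood at -0.59 ± 0.28 (adjusted p = 0.101) and miR-29b-3p, which represses collagens, at -0.24 ± 0.25 (adjusted p = 0.457). With slide as a block miR-5105 kept 3.04 (adjusted p = 0.000511), miR-370-3p 2.22, miR-770-3p 1.70, miR-221-3p -0.97 (adjusted p = 0.00109) and miR-130a-3p -0.77 (adjusted p = 0.0131), but miR-192-5p at -0.30 (adjusted p = 0.196) and miR-18a-5p at -0.76 (adjusted p = 0.143) lost the call. All 3 CsA arrays lay on slide 1 with 1 DMSO array; there 79 of 79 risers were positive with a median of 0.93 and 30 of 30 others negative with -0.53. Of all tested miRNAs 77 were separate where chance gives 2.38%; 44 of the 79 risers were above background on every DMSO array. The count was 72 without CsA50uM_48h replicate 3 and 173 without DMSO_48h replicate 6 (value-table names). The split moved with the scaling, while the median of all miRNAs shifted from 0.15 to -0.13 over all probes (41 higher and 71 lower), -0.01 after quantile normalisation (63 and 56) and -0.03 after normexp with quantile (69 and 71); on the value table's own values it was 42 and 62.

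**Figure D2:**
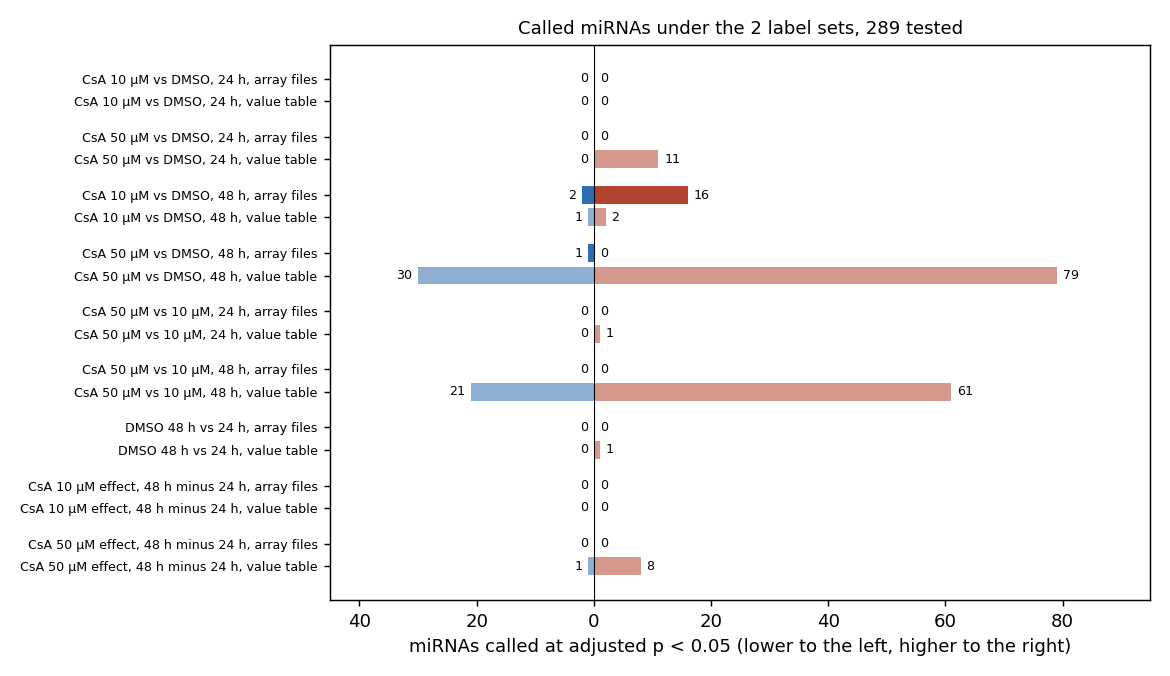
Number of miRNAs called higher or lower (x axis) in each comparison (y axis), with samples named by the array files or by the value table. At 50 µM and 48 h the counts were 0 and 1 by the files and 79 and 30 by the table.

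Under the value-table names 8 lists moved at 50 µM and 48 h under camera, all with adjusted p = 0.434 with an estimated correlation. Lower were the miR-23/24/27 clusters (median -0.86, 5 of 5 negative, 2 called, 4 adjusted over the list alone) and the let-7 family (-0.40, 9 of 9, 0 called), both with adjusted p = 0.021, and the miR-17/miR-92a list (-0.26, 11 of 11, with miR-93-5p, miR-18a-5p and miR-106b-5p called, adjusted p = 0.0272). With adjusted p = 0.0495 each followed hepatocyte-enriched (-0.19, miR-193a-3p and miR-192-5p), p53-responsive (-0.42), lipid (-0.24, miR-370-3p up, miR-27b-3p and miR-21a-5p down), miR-30 (-0.28, with miR-30e-5p at -0.44 ± 0.14) and, higher, Dlk1-Dio3 (0.63, mean 0.86, 5 of 5 positive, with miR-770-3p and miR-494-3p called). When slide was a block none of the 8 passed: adjusted p was 0.0547 for miR-23/24/27, 0.0587 for let-7 and miR-17/miR-92a, and 0.0894 for Dlk1-Dio3. Within slide 1 the medians were -0.28 for miR-23/24/27, -0.13 for let-7, 0.08 for miR-17/miR-92a, -0.09 for hepatocyte-enriched and 0.77 for Dlk1-Dio3. Not passing were endoplasmic reticulum stress-linked (-0.23, 2 members lower, adjusted p = 0.0654), miR-15/16 (-0.22), miR-29 (-0.24), NF-kB (-0.42) and Sfmbt2, whose median was 0.32 while the test leaned down.

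With both doses pooled, which holds under either naming, miR-221-3p fell by 0.99 ± 0.15 after 48 h (at least 1.99-fold, SE, n = 6 and 6, above background on 3 of 6 CsA arrays, adjusted p = 0.000492). All 6 CsA arrays lay below all 6 DMSO arrays. The Pparg-targeting miR-130a-3p fell by 0.76 ± 0.17 (1.69-fold, adjusted p = 0.0277) and miR-6378 rose by 1.34 ± 0.31 (2.53-fold, adjusted p = 0.0277). Values for miR-185-5p (-0.72 ± 0.18, adjusted p = 0.0518), miR-1906 (0.47 ± 0.12, adjusted p = 0.0567) and miR-122-5p (0.07 ± 0.09, adjusted p = 0.667) did not pass. With slide as a block miR-221-3p kept -0.89 ± 0.14 (adjusted p = 0.00218), while miR-6378 at 1.24 and miR-130a-3p at -0.59 did not (adjusted p = 0.244 each); within slides 1 and 3 the values were -1.22 and -0.66, 2.01 and 0.51, and -0.71 and -0.28. In limma 1 miRNA rose and 2 fell; 81 had an unadjusted p under 0.05 (56 higher), and 4 were separate where chance gives 0.216%. The median of all miRNAs was 0.10, and -0.16 when scaled over all probes, where 0 rose and 6 fell; quantile normalisation gave 3 and 2. Without any 1 array the count ran from 1 to 61; it was 38, 27 and 61 without the arrays filed as CsA10uM_48h replicate 1, CsA50uM_48h replicate 2 and DMSO_48h replicate 5, and 7 without CsA50uM_48h replicate 3. It was 1 without any of CsA50uM_48h replicate 1, CsA10uM_48h replicates 2 and 3 and DMSO_48h replicates 1 to 4. The count rose with the experiment number as a block, as given below, and the 3 calls stayed. The CsA and DMSO groups each held experiment numbers 1 to 3. If these mark a shared source, the 6 arrays of a group are not 6 independent samples.

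Pooled lists after 48 h moved down for let-7 (median -0.16, 9 of 9 negative) and miR-23/24/27 (-0.45, 5 of 5; 1 call adjusted over the list alone), each with adjusted p = 0.0412 and adjusted p = 0.619 with an estimated correlation. Blocked by slide they stood at -0.03 (adjusted p = 0.303) and -0.21 (adjusted p = 0.0727), and within slides 1 and 3 at -0.02 and 0.21 and at -0.18 and 0.07. After 24 h pooled limma called 0 miRNAs with 19 unadjusted p under 0.05 and 1 separate miRNA. Values were 0.89 ± 0.25 for miR-3096b-3p, -1.14 ± 0.32 for miR-6402 (above background on 2 of 5 CsA arrays), -1.23 ± 0.36 for miR-5100, -1.26 ± 0.37 for miR-212-3p (adjusted p = 0.21 each) and -0.46 ± 0.15 for miR-487b-3p (above on 1 of 5 CsA and 3 of 5 DMSO arrays, adjusted p = 0.26). The count was 4 without DMSO_24h replicate 1 and 3 without replicate 4. The Sfmbt2 cluster was lower (-0.32, adjusted p = 0.0419, adjusted p = 0.996 with an estimated correlation, with slide as a block -0.25, adjusted p = 0.0601; without DMSO_24h replicate 5 0.13).

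Doses were compared directly. By the files limma called 0 miRNAs at 24 h (3 unadjusted p under 0.05; 19 separate, chance 20%) and 0 at 48 h (17 unadjusted, 0 of them higher, lowest adjusted p = 0.826; 4 separate, chance 10%). At 48 h the count was 18 lower without CsA10uM_48h replicate 1. By the value table miR-770-3p was higher at 50 µM after 24 h by 0.75 ± 0.08 (SE, n = 2 and 3, above background on 1 of 3 arrays at 10 µM, adjusted p = 1.21e-05, with slide as a block 0.76, adjusted p = 9.06e-05; within slide 2 0.77), the only call among 26 unadjusted p under 0.05; the count was 3 without CsA10uM_24h replicate 2. Values near the floor narrow the SE of miR-770-3p here too. At 48 h by the table there were 61 higher and 21 lower miRNAs at 50 µM, 73 of them over 1.5-fold. Largest were miR-5105 (2.85 ± 0.49, 7.21-fold, adjusted p = 0.000283), miR-6243 (2.21 ± 0.38), miR-5121 (2.20 ± 0.61), miR-5128 (2.13 ± 0.51) and miR-370-3p (2.09 ± 0.45, adjusted p = 0.00188). Lower were miR-182-5p (-1.31 ± 0.17, 2.48-fold, adjusted p = 1.37e-05), miR-18a-5p (-1.31 ± 0.36), miR-96-5p (-1.16 ± 0.24), miR-19b-3p (-1.11 ± 0.36) and miR-331-3p (-1.01 ± 0.30, SE, n = 3 and 3), of which miR-182-5p, miR-18a-5p, miR-96-5p and miR-331-3p were above background on 2 of 3 arrays at 50 µM; miR-331-3p and miR-19b-3p lost the call with slide as a block (adjusted p = 0.0659 each). Within slide 1, miR-182-5p stood at -1.33 and miR-5105 at 3.01. The count was 45 without CsA10uM_48h replicate 1, 54 without replicate 2 and 49 without CsA50uM_48h replicate 3. The split was 34 and 7 scaled over all probes and 42 and 36 after quantile normalisation.

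Responses to both doses shared controls, which alone makes them alike. By the files the log2 changes of 289 miRNAs correlated across miRNAs with r = 0.745 at 24 h and 0.874 at 48 h. Simulations without any CsA effect gave 0.328 and 0.333, and separate control arrays for each dose gave 0.512 and 0.669. By the value table r was 0.641 and 0.243, against 0.331 and 0.332 in such simulations and 0.357 and -0.0615 with separate controls. The simulated noise was independent between miRNAs. How far r can stray without a CsA effect, where miRNAs of 1 array move together, is therefore not known. The cell-cycle miRNA miR-221-3p was called lower at both doses after 48 h under both namings, against the same 6 DMSO arrays. By the table miR-182-5p was called higher at 10 µM (0.82) and lower at 50 µM (-0.49, adjusted p = 0.0128) after 48 h. All 11 calls of 50 µM at 24 h by the table were called in the same direction at 48 h, and 17 of the 18 calls of 10 µM at 48 h by the files lay among the 109 of 50 µM by the table, miR-500-3p being the exception. These 2 comparisons share all 6 DMSO arrays and 2 of 3 CsA arrays, so much of that overlap comes from the same arrays. The miRNAs are not independent replicates.

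From 24 h to 48 h in DMSO, by the files, all 9 hepatocyte-enriched miRNAs were lower, with a median of -0.27 and mean of -0.32 (camera adjusted p = 4.14e-06, adjusted p = 0.383 with an estimated correlation). All 11 members of the growth-linked miR-17/miR-92a and paralogous clusters were higher, median 0.57 (adjusted p = 5.52e-06, adjusted p = 0.543 with an estimated correlation), and so were 5 of 5 of miR-23/24/27, median 0.47 and mean 0.64 (adjusted p = 0.0141, adjusted p = 0.543 with an estimated correlation). Adjusted over the list alone the counts were 0, 0 and 2. With slide as a block the medians were -0.30 (adjusted p = 3.86e-06), 0.50 (adjusted p = 4.62e-05) and 0.40 (adjusted p = 0.0495). Within slides 1, 2 and 3 they were -0.36, -0.10 and -0.46; 0.23, 1.15 and -0.13; and 0.16, 0.77 and 0.21. The last list lost its call without DMSO_24h replicate 5 (adjusted p = 0.071) or DMSO_48h replicate 3 (adjusted p = 0.059). With no filter on dim probes the hepatocyte-enriched list lost its call (median -0.245, camera adjusted p = 0.504), and its direction against the other miRNAs turned. In the value table the DMSO groups hold the same arrays under other replicate numbers, so only the pooled spread differs, and the values were adjusted p = 1.32e-06, 1.25e-05 and 0.0118 (0.235, 0.592 and 0.592 with an estimated correlation), and 3, 7 and 3 members passed adjusted over the list alone. Other medians by the files were 0.22 for let-7 (adjusted p = 0.0659), -0.06 for Sfmbt2, 0.22 for endoplasmic reticulum stress-linked, -0.23 for miR-29, -0.05 for miR-30, -0.05 for NF-kB and -0.04 for miR-15/16. The test leaned down for p53-responsive (median -0.14, mean 0.03), Dlk1-Dio3 (0.03 and -0.08) and lipid (0.12 and 0.19).

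**Figure D3:**
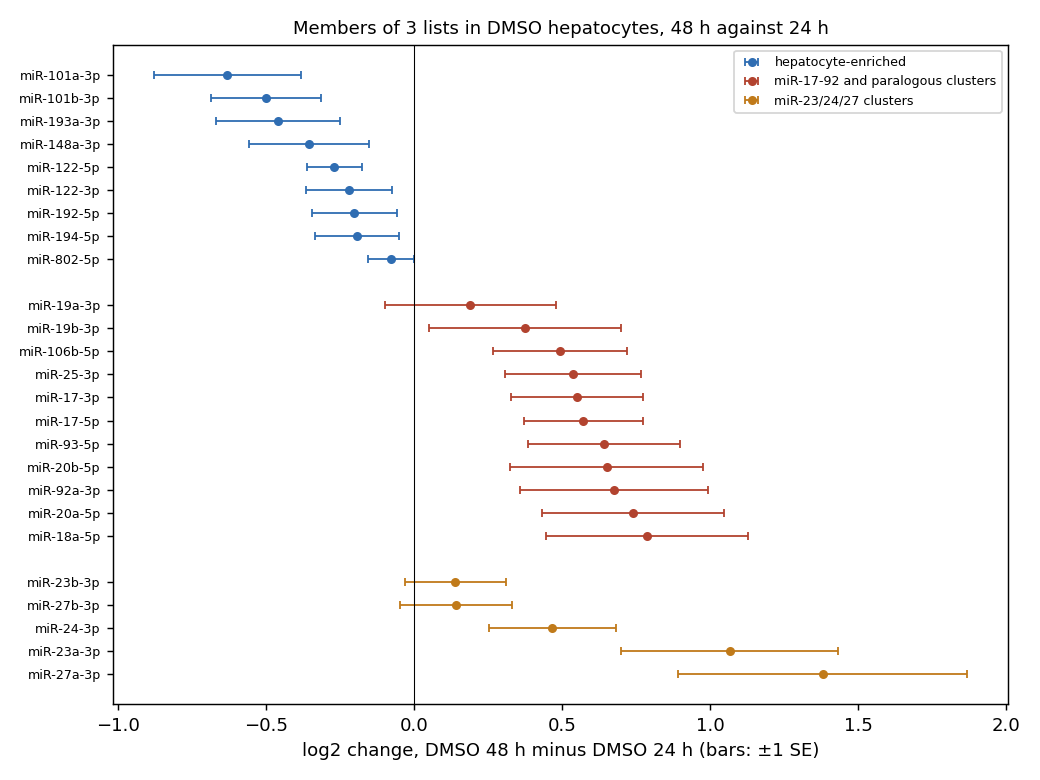
Log2 difference between 48 h and 24 h in DMSO (x axis) for each member of lists of miRNAs (y axis), by the array files, n = 6 and 5 arrays. The medians were -0.27 for hepatocyte-enriched and 0.57 for miR-17/miR-92a and paralogous clusters.

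Single miRNAs over culture time by the files gave 0 calls in limma, with 35 unadjusted p under 0.05 (25 higher) and 1 separate miRNA where chance gives 0.433%. The lowest adjusted p was that of miR-99b-5p (adjusted p = 0.105), which shares a transcript with let-7e and miR-125a. Named by the value table, miR-99b-5p rose by at least 0.91 ± 0.19 (log2, SE, n = 6 and 5, adjusted p = 0.0366, above background on 5 of 6 and 0 of 5 arrays, with slide as a block 0.96, adjusted p = 0.0178; within slides 0.48, 1.51 and 0.66). That single call was lost without 7 of the 11 arrays, and the count was 8 without DMSO_24h replicate 1, 7 without DMSO_24h replicate 3, and 4 and 5 without DMSO_48h replicates 6 and 5 (value-table names). By the files the count was 1 without DMSO_48h replicate 5. Under both namings more miRNAs were called with the experiment number as a block, as given below.

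Whether the CsA effect differed between 48 h and 24 h was tested as an interaction. By the files limma called 0 miRNAs at 10 µM (12 unadjusted p under 0.05, lowest adjusted p = 0.832) and 0 at 50 µM (1 unadjusted, lowest adjusted p = 0.978); at 10 µM the count was 10 without CsA10uM_48h replicate 1. By the value table the count was 0 at 10 µM (3 unadjusted) and 9 at 50 µM (39 unadjusted), 8 with a larger effect at 48 h. These were led by miR-6351 (1.41 ± 0.14, adjusted p = 2.17e-06), miR-6378 (1.29 ± 0.25, adjusted p = 0.00332), miR-452-5p (1.07 ± 0.24, adjusted p = 0.0135), miR-450a-2-3p (1.06 ± 0.13, adjusted p = 1.48e-05) and miR-770-3p (0.92 ± 0.10, adjusted p = 4.27e-06; SE, n = 3, 6, 2 and 5). Several lay near background: miR-6351 was above it on 0 of 11 DMSO arrays, 2 of 3 CsA arrays at 48 h and 1 of 2 at 24 h, miR-450a-2-3p on 1 of 6 and 1 of 5 DMSO arrays, and so was miR-452-5p. For these and for miR-770-3p the floor narrows the SE, so their small p-values overstate the precision. The only smaller effect was that of miR-361-5p (-0.69 ± 0.18, adjusted p = 0.0472), lost with slide as a block (-0.55, adjusted p = 0.243). The count was 17 without CsA50uM_48h replicate 1 and 30 without DMSO_48h replicate 6 (value-table names). It was 2 with the lower floor, with total gene signal and with normexp, and 1 from the value table's own values. It rose with the experiment number as a block, as given below.

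**Figure D4:**
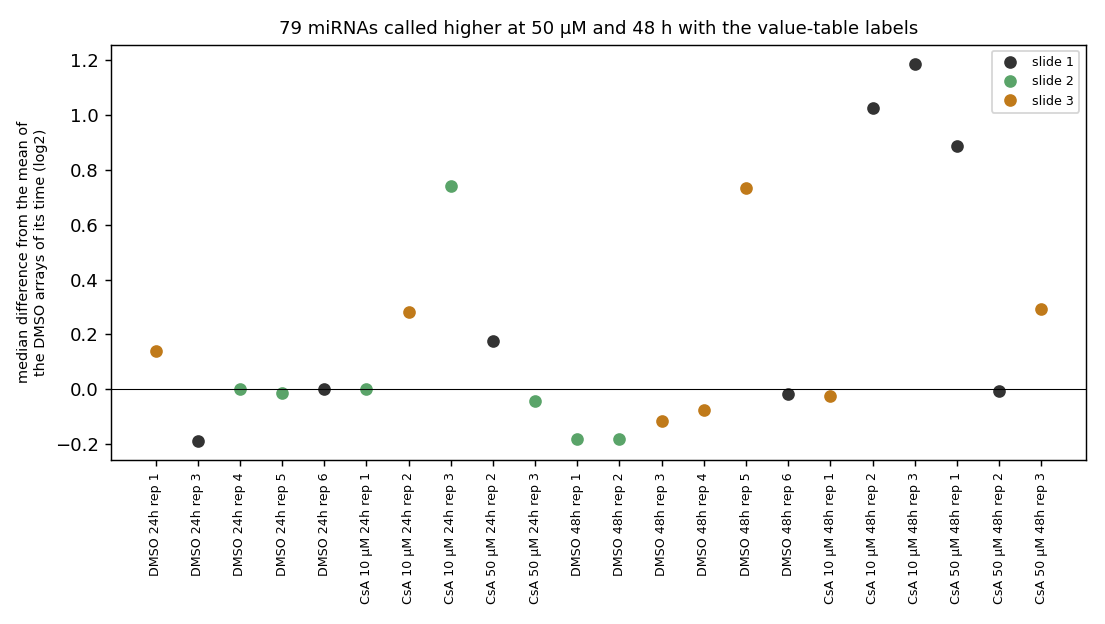
Median log2 difference from the DMSO mean of the same time (y axis) of the 79 miRNAs that the value-table names call higher at 50 µM and 48 h, for each array (x axis, array files' names), coloured by slide. The arrays filed as CsA10uM_48h replicates 2 and 3 stood at 1.03 and 1.19 and CsA50uM_48h replicates 2 and 3 at -0.01 and 0.29.

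Markers of other cells and of low oxygen were looked at singly. By the files, miR-210-3p, the hypoxia miRNA, stood at -0.46, -0.24, -0.20 and -0.53 (10 µM and 50 µM at 24 h, then at 48 h) and at -0.76 over time in DMSO; by the table the CsA values were -0.37, -0.37, -0.48 and -0.25. The leukocyte miRNA miR-155-5p stood at 0.25, -0.15, 0.57 and 0.39 by the files and at -0.10, 0.38, 0.23 and 0.73 by the table, where the last passed. The 1 mesenchymal and stellate member had -0.05, -0.23, 0.32 and 0.24 by the files and -0.28, 0.11, 0.05 and 0.51 by the table, and the 1 endothelial member 0.31, -0.14, 0.40 and 0.15 and 0.19, 0.03, 0.38 and 0.18. None of these passed by the files.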

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

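Each group of 4 to 10 arrays was searched for a single array far from the others, by the gap to its nearest neighbour divided by the group's range. Chance alone sets apart about 1 in 20 such groups. Of 94 tests of a named miRNA in a DMSO group 11 exceeded the limit, and of 8 tests of an array measure 3 did. The tests of the 79 higher miRNAs against slide and against scaling were chosen after the result was seen. The test against array brightness was written before.

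Of the 11, 8 came from 1 array, the DMSO array filed as 48 h replicate 5. It lay above the other 5 for miR-370-3p of the Dlk1-Dio3 region (0.718), for miR-494-3p of the same region (0.627), and for miR-1306-3p (0.637), miR-3102-3p (1.00), miR-452-5p (0.876), miR-5119 (0.866), miR-5121 (0.699) and miR-5622-3p (0.712). The others were miR-27b-3p on DMSO_24h replicate 5 (0.781), miR-450a-2-3p on DMSO_24h replicate 1 (1.00) and miR-770-3p on DMSO_48h replicate 2 (0.949). The ratios of 1.00 arose because all other arrays of the group lay at the floor, so they show little, and miR-450a-2-3p was not above background on the array that stood apart. Among array measures, the percent of outlier spots stood apart on DMSO_24h replicate 3 (0.969) and DMSO_48h replicate 6 (0.8288), and the negative control mean on DMSO_48h replicate 1 (0.974). The negative controls, which no comparison used, averaged 215.3 on CsA10uM_24h replicate 3, above every DMSO array.

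A difference between 48 h and 24 h in the effect of 50 µM CsA passed its own test for 9 miRNAs under the value-table names, and for 2 with the lower floor, total gene signal or normexp and 1 with the value table's own values. The effect was larger at 48 h for miR-6351 (1.41), miR-6378 (1.29), miR-452-5p (1.07), miR-450a-2-3p (1.06), miR-770-3p (0.92), miR-1931 (0.84), miR-1945 (0.75) and miR-6418-5p (0.70). It was smaller for miR-361-5p (-0.69). The entries miR-1931, miR-1945 and miR-6418-5p were named after their values were seen. Under the files' names 0 miRNAs passed this test.

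The 79 miRNAs that rose at 50 µM and 48 h under the value-table names also stood high on the DMSO array filed as 48 h replicate 5, with a median 0.73 above the DMSO mean. The same set stood at 0.89, 1.03 and 1.19 on the 3 treated arrays, at 0.74 on CsA10uM_24h replicate 3 and at -0.19 to 0.14 on the other DMSO arrays. The median change of the 79 was 0.998 with slide as a block (median SE 0.249) against 1.03 without. This alone decides little, because the 79 were picked on the treated arrays, all on slide 1 with 1 DMSO array of 48 h. Against a slide difference, the 3 DMSO arrays of slide 1 stood at a median of -0.041 from the other DMSO arrays for the 79. That value had time as a term and carries no SE. For brightness of the arrays, the upper 95% bound of the shift it predicts was 0.497, below the 1.03. This excludes little, because the slope came from DMSO arrays with a log2 75th percentile of 7.56 to 8.54. The treated array filed as CsA10uM_48h replicate 3 lay beyond them at 9.24, and the 79 were picked on the treated arrays. A choice of scaling stays open as well, as a cause of part of the rise. The lowest median of the 79 under another scaling was 0.266 (median SE 0.0711), above 0, but they were picked under the main scaling, so this excludes little. Over all probes the median was 0.499, with 41 higher and 71 lower calls against 79 and 30, and after quantile normalization it was 0.656. A response to CsA stays open as a hypothesis found on the same data, and it leaves the DMSO array unexplained.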

How the results depend on the processing

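The alternatives with the value-table names, with both doses pooled and without the 3 arrays that stand apart were chosen after the data were seen; the others were planned. Over 529 recomputed counts of called miRNAs, all that moved by more than 1.5 times are given below. Of 3841 values of named miRNAs 3396 counted as the same, 333 lost their call, 48 gained 1, 62 untested within-slide values moved and 2 turned. Tested values counted as the same where they stayed on their side of the threshold, uncalled ones included. A change of sign counted as a turn only where a call was involved, so sign changes among uncalled values are within the 3396. Within-slide values counted as the same by their distance from the fitted value. Of 3872 list tests 3502 counted as the same by the rule for tested values, 159 lost a call, 184 gained 1 and 27 turned. The counts given below are of called miRNAs, by the files unless the table (value-table names) or pooled doses are named, and except where a smaller or larger set of miRNAs or arrays explains it, the cause was not tested. Of all probe-array pairs 14.4% were well above background.

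Several counts moved with the scaling. With the 75th percentile over all probes, 10 µM at 48 h gave 0, by table names 0, the doses at 48 h by table names 41 (34 higher, 7 lower), time in DMSO by table names 0, the 50 µM interaction by table names 4 and pooled doses at 48 h 6. There miR-500-3p at 10 µM and 48 h turned to -0.00295. With quantile normalization, 10 µM at 48 h gave 3, 50 µM at 48 h 0, 10 µM at 48 h by table names 0, the doses at 24 h by table names 2, time in DMSO by table names 0 and pooled doses at 48 h 5. With normexp background and quantile normalization the same results gave 1, 0, 0, 0 and 0 up to time in DMSO, and the 50 µM interaction by table names 2. With total gene signal, 10 µM at 48 h gave 0, 50 µM at 48 h 2, by table names 10 µM at 48 h 0, the doses at 24 h 0 and the 50 µM interaction 2, and pooled doses at 48 h 10. With the mean over all probes of a miRNA, time in DMSO by the table gave 0 and the 50 µM interaction by table names 14.

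Treatment of dim probes mattered too. With a floor 0.5 times as high, 10 µM at 48 h gave 10, time in DMSO 1, by table names 10 µM at 48 h 1 and the 50 µM interaction 2, and pooled doses at 48 h 11. With the filter above background on every array of a group, 10 µM at 48 h gave 2, and by the table time in DMSO 0 and the 50 µM interaction 2, with fewer miRNAs tested. With no filter on dim probes all 1247 miRNAs were tested: 10 µM and 50 µM at 48 h gave 0 and 0, time in DMSO 926 (15 higher, 911 lower), by table names 50 µM at 24 h 2, the doses at 48 h 51 and time in DMSO 941 (28 higher, 913 lower), and pooled doses at 48 h 1. Most of those probes lay at the floor or in background, so the calls over time in DMSO do not show real decreases.

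With no filter on dim probes the lists and the miRNAs they are set against were larger, and 21 list tests turned: the direction of a list against the other miRNAs changed, while several of its own medians kept their sign. Medians at 10 µM and 24 h were 0.0107 for hepatocyte-enriched, 0.0479 for miR-29 and 0 for Sfmbt2, and -0.0156 for miR-30 at 50 µM and 24 h. At 48 h they were -0.557 for miR-23/24/27 at 10 µM, and at 50 µM -0.00048 for hepatocyte-enriched, 0.000511 for miR-17/miR-92a, -0.0594 for lipid and -0.174 for let-7. Over time in DMSO they were -0.245 for hepatocyte-enriched, 0 for lipid and -0.0457 for miR-30, and 0 for lipid by the table. By the table at 50 µM and 24 h they were -0.109 for hepatocyte-enriched, 0 for lipid, 0.0684 for let-7, 0.0248 for miR-30 and -0.0293 for miR-23/24/27, and 0.000264 for lipid at 10 µM and 48 h. With pooled doses at 24 h they were 0.0157 for hepatocyte-enriched and 0.029 for miR-29.

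Whether the numbers in the labels pair the arrays is not given in the sources used here. The residual correlation within a replicate block was over 0.1 in 7 of 11 pairs (lowest -0.308, median 0.179), and by the table in 10 of 11 (lowest 0.038, median 0.288). Over all pairs from the same experiment the median correlation was 0.145, and 0.255 by table names, against -0.094 and -0.167 for other pairs, a hint from the data and not from the design. With the replicate block by experiment number, 10 µM at 24 h gave 1, 10 µM at 48 h 29, 50 µM at 48 h 2 and time in DMSO 7. By table names 50 µM at 24 h gave 17, time in DMSO 29 and the 50 µM interaction 30, and pooled doses 1 at 24 h and 24 at 48 h. With the replicate block by IC20 tag and experiment number, 10 µM at 48 h gave 3 and 50 µM at 48 h 0. By table names 10 µM at 24 h gave 1, the doses at 48 h 1.3e+02 (74 higher, 58 lower), time in DMSO 20 and the 50 µM interaction 19, and pooled doses at 48 h 11. With slide as a fixed block, 10 µM at 48 h gave 3 and pooled doses at 48 h 1.

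Values and names were exchanged next. With the authors' value table, 50 µM at 24 h gave 8, 10 µM at 48 h 0, 50 µM at 48 h 104 (42 higher, 62 lower), the doses at 48 h 69 (34 higher, 35 lower) and the 50 µM interaction 1, where both the sample names and the values differ from the first fit. Against the fits by the table the authors' value table gave 0 for 10 µM at 48 h, 0 for the doses at 24 h, 0 for time in DMSO and 1 for the 50 µM interaction, and pooled doses at 48 h 10. There the miR-17/miR-92a median at 10 µM and 48 h turned to 0.294 and miR-770-3p to -0.897. With the labels of the value table, 50 µM at 24 h gave 11, 10 µM at 48 h 3, 50 µM at 48 h 109, the doses at 24 h 1 and at 48 h 82, time in DMSO 1 and the 50 µM interaction 9. The correlation of the responses to both doses was 0.641 at 24 h and 0.243 at 48 h with these labels. With controls split by IC20 tag it was 0.512 and 0.669, and by table names 0.357 and -0.0615.

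Fewer arrays changed counts as well. With the 3 arrays that stand apart left out, 10 µM at 48 h gave 74 (65 higher, 9 lower), by table names 50 µM at 24 h 6 and at 48 h 182 (119 higher, 63 lower), the doses at 48 h 1.2e+02 (88 higher, 36 lower), time in DMSO 2 and the 50 µM interaction 21, and pooled doses at 48 h 72. The Sfmbt2 median at 24 h then turned to 0.0663 at 10 µM and 0.196 with pooled doses. With controls of the same IC20 tag, 10 µM at 48 h gave 3, by table names 10 µM at 24 h 1 and 50 µM at 24 h 1, and the Sfmbt2 median at 10 µM and 24 h turned to 0.244. With only the groups compared, 10 µM at 48 h gave 1, 50 µM at 48 h 2, and by the table the doses 0 at 24 h and 1.2e+02 at 48 h (73 higher, 51 lower) and time in DMSO 0.

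Leaving out 1 array at a time (a lone array was assumed to vary like the other groups) gave these ranges. Counts ran from 0 to 1 for 10 µM at 24 h, 0 to 0 for 50 µM at 24 h, 0 to 88 for 10 µM at 48 h and 0 to 1 for 50 µM at 48 h. The doses gave 0 to 0 at 24 h and 0 to 18 at 48 h, time in DMSO 0 to 1, and the interactions 0 to 10 at 10 µM and 0 to 0 at 50 µM. By the table the ranges were 0 to 0 and 1 to 19 at 24 h, 0 to 4 and 72 to 173 at 48 h, 1 to 3 and 45 to 83 for the doses, 0 to 8 for time in DMSO, and 0 to 0 and 6 to 30 for the interactions. Pooled doses gave 0 to 4 at 24 h and 1 to 61 at 48 h. The Sfmbt2 median at 24 h ran from -0.397 to 0.200 at 10 µM and from -0.413 to 0.135 with pooled doses, turning only without DMSO_24h replicate 5. The fall of miR-221-3p at 48 h with pooled doses kept its direction and its call in every tested alternative, from -0.334 with normexp background to -1.98 with total gene signal.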

Other observations

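From 24 h to 48 h in DMSO alone, all 9 hepatocyte-enriched miRNAs stood lower and all 11 miRNAs of the growth-linked miR-17/miR-92a clusters higher, with medians of -0.27 and 0.57 (limma camera adjusted p = 4.14e-06 and 5.52e-06, and 0.383 and 0.543 with an estimated correlation). The hepatocyte-enriched call was lost with no filter on dim probes (camera adjusted p = 0.504). Within slide 3 the miR-17/miR-92a median was negative. In the miR-23/24/27 clusters the largest values were those of miR-23a-3p (1.07 ± 0.37) and miR-27a-3p (1.38 ± 0.49, SE, limma adjusted p = 0.234 each), which lie in 1 transcript.

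The array files and the value table put 8 CsA arrays under opposite doses, and both tests of this were written before their result was seen. The reference was the difference between 50 µM and 10 µM in experiment 1 at 48 h, where both sources give the same names. If the doses were exchanged among the array files, the filed difference of the other 4 pairs should run against it, and it did in 4 of 4 pairs (r = -0.127, -0.629, -0.900 and -0.805 across miRNAs). If the doses were exchanged among the columns of the value table, the pairs should run with it, and 0 of 4 did. The reference set an array on slide 1 (50 µM) against 1 on slide 3 (10 µM), so a slide difference can enter r. The pair with r = -0.805 lay the other way round, on slides 3 and 1. There slide alone would give a negative r. The pairs with -0.629 and -0.900 each lay on 1 slide, and the weak -0.127 came from slides 1 and 3. The second explanation, of exchanged value-table columns, stays open all the same, since the reference rests on 1 array per dose and miRNAs are not independent replicates. The report keeps both namings.

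The fall of miR-221-3p after 48 h of CsA did not depend on the naming. The tests against slide and scaling were chosen after it was seen, the 1 against background before. A difference between slides was argued against, as the pooled change was -0.889 with slide as a block (SE 0.143) and -1.22 and -0.66 within slides 1 and 3. A choice of scaling was argued against, as the smallest fall was -0.334 (SE 0.0659). Signal near background cannot be told apart from part of the size: miR-221-3p was well above background on 9 of 12 arrays, and CsA50uM_48h replicates 1 and 2 lay at the floor.

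Other splits of the same arrays were tried, a test written before the results were seen. At 10 µM and 48 h, 4 of 84 splits called as many as the real 18, a share under 0.05 that was not adjusted over the split tests. The 18 calls fell to 0 without CsA10uM_48h replicate 2 or replicate 3, and over all probes. Another split, that of CsA10uM_48h replicates 2 and 3 with DMSO_48h replicate 5 against the rest, called 10.72 times the real count, and this points to a structure of the samples other than the filed groups. At 50 µM and 48 h, 3 of 84 splits called as many as the real 1, which was lost without CsA50uM_48h replicate 1 or replicate 2, and the highest other of 76 is again a sign of such structure. With doses pooled at 48 h, 2 of 100 splits reached the 3 calls, and the highest other was 158. These shares were not adjusted either, so they carry little weight. Where the real count is 0 every split calls as many, so the splits say nothing about chance: 10 µM at 24 h (56 of 56 splits, highest other 14), time in DMSO (100 of 100, highest 32), the 10 µM interaction (100 of 100, highest 174) and doses pooled at 24 h (100 of 100, highest 6). The 50 µM against 10 µM comparison at 48 h has 10 splits, too few for a share under 0.05, with 0 real calls and 77 as the highest other (10 of 10 as large).

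Under the value-table names chance cannot be excluded for the 109 calls of 50 µM at 48 h, as 5 of 84 splits called as many and the highest other, DMSO_48h replicates 1, 2 and 4 (value-table names) against the rest, called 1.42 times the real count. The blocked median of its 79 higher miRNAs was 0.998. The same holds for the 3 calls of 10 µM at 48 h (5 of 84, highest other 108) and for the 1 call over time in DMSO (11 of 100, highest 63). With a real count of 0 the splits again say nothing at 10 µM and 24 h (56 of 56, highest 27) and in the 10 µM interaction (100 of 100, highest 69). The comparison of doses at 48 h has too few splits for a share under 0.05, with 82 real calls, 0 as the highest other and 1 of 10 as large.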
